A study of Arabidopsis thaliana with 8 samples.

How the data were processed

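Embryos of Arabidopsis thaliana were profiled on 2-colour arrays at 3 d and 6 d after pollination, with 4 arrays per stage. Each array carried RNA from embryos of the cross M0191 (female) by bdl (male), called the bdl cross here, in 1 channel and RNA from embryos of M0171 (female) by Col-0 (male), called the Col-0 cross, in the other. Per the labels' protocols, total RNA was extracted with a micro-scale column kit, amplified as antisense RNA and coupled to NHS-ester dyes, and the replicates were biological. The bdl cross was in Cy5 on replicates 1 and 2 and in Cy3 on replicates 3 and 4 of each stage, per the labels. Scanner, image software, background correction and normalization are not given in the sources used here, nor are slides or scan dates, so none was tested as a batch. Array design names and gene loci were taken from the annotation columns of the 3 d files.

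For the 3 d arrays, the deposited files held 1 intensity per spot and cross on a linear scale. Their values showed that the authors had already subtracted background and balanced the channels: the median log2 ratio lay within 0.02 of 0 on each array, and blank spots lay near 0. Normexp background correction and loess normalization, planned for raw signals, were therefore not applied in the chosen setting. For the 6 d arrays, only the deposited table of log2 ratios was analysed; scanner files of that stage were not analysed here. The table has 28399 rows and covers all 8 arrays. Its scale and direction were found by setting the 3 d columns against the 3 d intensities. All 24661 rows with at least 2 values at 3 d matched exactly 1 spot within 1e-06 (largest difference 4.71e-08), as log2 of the bdl cross over the Col-0 cross with no centring added; 0 rows matched with the sign turned and 0 with the arrays shifted by 1. A further 2267 rows with 1 value at 3 d and 1471 rows with none were left unnamed. The 6 d columns were taken to follow the same convention, which was not checked against intensities; their direction is known only that far. The column medians were −0.014, 0.004, 0.003 and −0.006 at 3 d and −0.032, −0.034, −0.020 and −0.026 at 6 d. The number of columns of no known sample was 0. Pairs of arrays with equal values were searched for, and the share of equal values was 0% in every pair.

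Gene names came from the locus of each probe and the RefSeq gene table of assembly TAIR10.1, used for names alone because the files name no build; no coordinates were taken from it. Of 24648 loci on 27387 gene probes, 24467 (99.3%) were found in that table. Another 191 spike or control reporters and 738 print-control spots were left out, and so were 75 probes of microRNA stem-loops with no locus. Where a locus had several probes (1645 loci had 2 or more), the gene took the probe of highest mean intensity at 3 d, at both stages.

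At 3 d, a probe was kept where either channel exceeded the 95th percentile of the array's blank spots on at least 2 of the 4 arrays. The blank spots stood in for the planned rule on foreground and background, since the files give neither. This left 22089 probes of 19839 loci, of which 19229 genes had values on at least 3 arrays, with both dye orientations, and were tested. At 6 d a value on at least 3 arrays, with both dye orientations, was required, which 19986 genes met. Log2 ratios were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with a probe-specific dye term, and adjusted by the Benjamini-Hochberg method; a gene was called at an adjusted p under 0.05. Adjusted p-values of genes are from limma throughout. The difference between stages was tested in a fit of all 8 arrays from the value table, with a dye term shared by both stages and no replicate block. Tables were handled with the data.table package (1.17.8), and Python 3.11.15 with matplotlib 3.10.9 drew the figures. Errors after ± are standard errors of these fits unless an SD is named.

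The lists tested were Aux/IAA genes, auxin response factors (ARF), GH3 enzymes with auxin receptors, auxin transport, auxin biosynthesis, MP/BDL target genes, suspensor bHLH genes of the auxin network, zygote and suspensor genes, root pole and ground tissue, shoot apex and cotyledon, vascular genes, epidermis, embryo maturation regulators, seed storage and oil body, photosynthesis, cell division and DNA replication, cytokinin response, gibberellin metabolism, SAUR genes and cytosolic ribosomal proteins. Markers of tissues or handling that isolated embryos could carry were tested beside them: endosperm, seed coat, and heat shock with wounding. Some genes stand in several lists, among them PIN7, AHP6, HB-8, TMO6, SCZ, ARF9 and ARF13. The suspensor bHLH list also holds IAA10, IAA30 and ARF9, which are not bHLH genes. The values of 1 list member are not reported here, though it counts in its lists. Camera compared each list with all other genes at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 23 lists and at least 3 measured members. It was repeated with a correlation estimated per list. That form takes its p-values from the few residual degrees of freedom of the fit, and the preset form from the number of genes. A list that fails with an estimated correlation may fail for that reason alone. Fry tested whether the members of a list changed in a shared direction, without comparing them with other genes.

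Genes were named by a rule. Per stage, these were the 10 largest rises and 10 largest falls among genes called with the same sign on all 4 arrays; for the stage difference, the 5 largest per direction; from each list, IAA12, MP and up to 4 members of smallest p; and the 5 genes of largest mean change called at both stages. Groups, tests, lists, the naming rule and most alternatives were fixed before the data were examined; the blank-spot filter and 5 further alternatives were not. The alternatives covered normalization, dim-probe filters, the dye term, the value table in place of the 3 d files, averaging over probes, a larger effect, the estimate of spread, list correlations and each array left out. Uncorrected values, plain background subtraction and print-tip loess were not run, because the files hold no background columns or blocks.

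The fits were tested on simulated data for the 19229, 19986 and 18843 genes of the 3 d, 6 d and stage-difference fits. With 200 of the 3 d genes changed, limma made 84 calls, of which 6 were unchanged genes, and called 0%, 24%, 56% and 76% of changes of 0.5, 1, 2 and 4 on the log2 scale. With 200 of the 6 d genes changed it made 69 calls, 1 of them unchanged, and called 0%, 22%, 42% and 72% at those sizes. For the stage difference it made 109 calls, 12 of them unchanged, and called 10%, 44%, 62% and 78%. With 6000 genes changed, calls numbered 4925, 4815 and 4533, of which 180, 227 and 158 were unchanged genes. A shift of 1 on the log2 scale added to the photosynthesis list was recovered by camera at both stages, and 0 of the 22 other lists were called. Only the preset correlation was simulated, so the power of camera with an estimated correlation is not known. In that simulation genes varied independently and 200 were changed. It therefore does not show how often camera calls lists of correlated genes or where many genes change.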

Results

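Gene expression was measured in isolated Arabidopsis embryos on 2-colour arrays, on which RNA from a pair of crosses competed for the same spots. Embryos from the stock line M0191 crossed as female with bdl were set against embryos from M0171 crossed as female with Col-0, the laboratory wild type. Embryos were taken 3 d and 6 d after pollination, with 4 arrays per stage, and the dyes were exchanged on replicates 3 and 4. The name bdl is that of bodenlos, a line known for a stabilised form of the Aux/IAA repressor IAA12 (BDL), which binds and restrains the auxin response factor MP. The labels do not describe M0191 and M0171 further, and both the female and the male parent differed between the crosses, so no difference can be assigned to 1 parent. Positive log2 ratios are higher in the bdl cross, and values after ± are standard errors over 4 arrays unless an SD or another n is given.

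On the 3 d arrays, 22337, 24317, 22786 and 25331 of 27530 gene spots held values on replicates 1 to 4, and 74.3%, 78.0%, 76.7% and 81.2% of gene spots lay above the blank spots. Median signals were 344, 351, 319 and 320 for the bdl cross and 334, 350, 321 and 315 for the Col-0 cross. Blank spots had median log2 ratios of 1.28, −1.18, −1.32 and 0.79 on replicates 1 to 4, which pairs 1 with 4 and 2 with 3 and not by the labels' dyes. At 6 d, where log2 ratios alone were analysed, 26342, 24778, 23517 and 24527 rows held values. The SD of log2 ratios over genes was 1.01, 0.88, 0.92 and 0.89 at 3 d and 1.22, 1.42, 1.32 and 1.27 at 6 d. The number of arrays limits the precision of every value. The p-values measure the spread between these samples, which the design text calls biological replicates.

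IAA12 (AT1G04550), the gene affected in bdl, was 10.6-fold higher in the bdl cross at 3 d, with a log2 ratio of 3.403 ± 0.11 (SD, n = 4; arrays 3.57, 3.39, 3.34 and 3.32; limma adjusted p = 0.0224). At 6 d it was 1.24-fold higher, with a log2 ratio of 0.31 ± 0.05 (SD, n = 4; arrays 0.30, 0.39, 0.26 and 0.30; limma adjusted p = 0.0283). The difference between the stages, 6 d minus 3 d, was −3.09 (adjusted p = 1.09e-05). Its 3 probes read 3.403, 3.20 and 1.36 at 3 d but 0.31, 0.70 and −0.61 at 6 d, and the mean over probes was 2.65 at 3 d (adjusted p = 0.0236) and 0.14 at 6 d (adjusted p = 0.192). Leaving out 1 array with the dye term kept gave 3.36 to 3.45 at 3 d and 0.29 to 0.34 at 6 d, with adjusted p of 0.112 to 0.154 and 0.0822 to 0.111, so the call ended each time. MP (AT1G19850), the response factor that BDL binds, fell at both stages, 1.77-fold at 3 d (−0.82 ± 0.11, adjusted p = 0.0408) and 2.27-fold at 6 d (−1.18 ± 0.15, adjusted p = 0.0108).

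**Figure D1:**
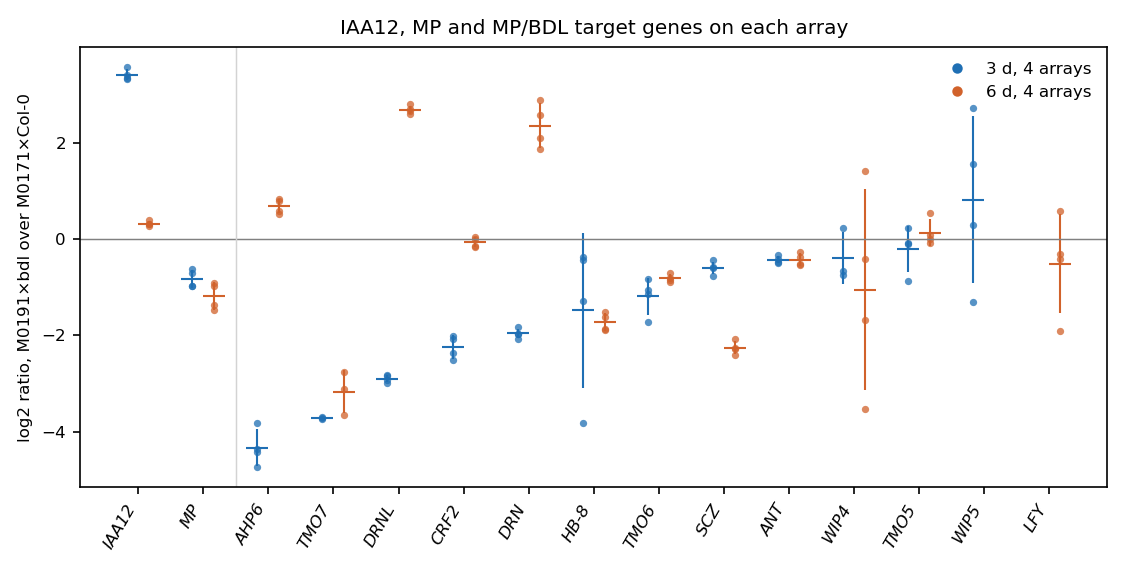
Log2 ratio of the bdl cross over the Col-0 cross (vertical axis) for IAA12, MP and MP/BDL target genes (horizontal axis) at 3 d (blue) and 6 d (orange), with 1 point per array and bars for the mean and SD. IAA12 stands at 3.403 at 3 d and 0.31 at 6 d, while DRNL lies at −2.90 at 3 d and at 2.68 at 6 d.

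The comparison at 3 d asked which genes differed between the crosses in young embryos. Camera called lists of seed storage genes as higher and of MP/BDL target and auxin transport genes as lower, but none of them with an estimated correlation (adjusted p = 0.257 for each). Of 19229 genes tested, 1349 rose and 1178 fell, 2527 in all (13.1%), of which 396 rose and 264 fell by at least 1 on the log2 scale. Among the largest rises were the 2S albumin genes SESA3 (24.4-fold, 4.61 ± 0.07) and SESA2 (22.3-fold), the LEA-domain gene AT4G21020 (24.1-fold), the oleosin gene OLEO4 (21.0-fold), the vicilin-like gene PAP85 (20.5-fold) and LEA7 (20.1-fold). The stem-cell peptide gene CLV3 read 4.33 to 5.73 with 1 array left out, but its Col-0 signal lay above blank spots on 1 of 4 arrays, so no fold is given, and its 3 probes differed, at 5.03, 2.32 and −0.08. Among the largest falls were the growth-regulating factor GRF5 (35.2-fold, −5.14 ± 0.69), the cytokinin signalling inhibitor AHP6 (20.1-fold, −4.33 ± 0.15), AT1G15760 (10.1-fold), the auxin influx carrier LAX2 (8.62-fold), the YABBY factor FIL (8.38-fold) and IAA19 (8.19-fold). The weaker signal lay above blank spots on 2 of 4 arrays for AT4G21020, OLEO4, PAP85, GRF5, AT1G15760, AT5G44630, T5L1, JKD, YUC10 and SAUR29. GRF5 and AT1G15760 lost their calls with no filter on dim probes (adjusted p = 0.0505 and 0.0509), and GRF5 read −5.86 to −4.42 with 1 array left out.

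With any of the 4 arrays left out and the dye term kept, limma had 1 residual degree of freedom and called 0 genes (4610 to 5358 at an unadjusted p under 0.05), although all 2445 to 2477 called genes still tested kept their sign. The count was 5375 with both channels above blank spots on all 4 arrays, 5078 without the dye term, 4872 with a dye term that followed the blank spots and 5732 with an intensity trend in the spread.

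MP/BDL target genes, known from other work to respond to MP, fell together at 3 d. Of 13 measured targets, 9 fell, 0 rose and 4 did not pass, and 9 fell adjusted over the list alone (median −1.48, camera adjusted p = 2.74e-05; adjusted p = 0.257 with an estimated correlation). The AP2-type factors DRNL and DRN, which act in cotyledon formation, fell 7.44-fold (−2.90 ± 0.07, adjusted p = 0.0224) and 3.89-fold (−1.96 ± 0.07, adjusted p = 0.0224), the cytokinin response factor CRF2 fell 4.73-fold (−2.24 ± 0.13, adjusted p = 0.0277), and the Dof factor TMO6 fell 2.28-fold. CRF2 lost its call in the mean over its probes (−1.82, adjusted p = 0.109). TMO7, a small bHLH gene and MP target named here after its values were seen, read −3.71 ± 0.09 (n = 3, adjusted p = 0.0281).

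The auxin transport list was also called lower at 3 d, and the auxin biosynthesis list higher, at the preset correlation alone. Of 14 transport genes, 6 fell and 2 rose, with 7 and 2 adjusted over the list alone (median −0.51, camera adjusted p = 0.0165; adjusted p = 0.257 with an estimated correlation). The influx carriers LAX2 (−3.11 ± 0.20) and LAX1 (−2.32 ± 0.11) and the efflux carrier PIN7 (−0.94 ± 0.06) fell. In the mean over probes LAX1 read −1.42 and PIN7 lost its call (−0.33, adjusted p = 0.300). Of 9 biosynthesis genes, 4 rose and 0 fell, with the same counts adjusted over the list alone (median 0.83, camera adjusted p = 0.0166; adjusted p = 0.257 with an estimated correlation). These were the tryptophan aminotransferase gene TAA1 (2.85-fold, 1.51 ± 0.06) and the flavin monooxygenase genes YUC4 (7.58-fold, 2.92 ± 0.19), YUC1 (5.50-fold, 2.46 ± 0.20) and YUC10 (3.37-fold, 1.75 ± 0.22).

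The remaining auxin lists did not pass at 3 d. Of 22 Aux/IAA genes, 1 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.0632; adjusted p = 0.284 with an estimated correlation). IAA19 (−3.03 ± 0.11), IAA26 (−2.36 ± 0.28) and IAA20 (−0.75 ± 0.06) fell beside the rise of IAA12. Among 14 ARF genes, 1 rose and 5 fell, with 1 and 6 adjusted over the list alone (camera adjusted p = 0.288; adjusted p = 0.647 with an estimated correlation). ARF13 rose (0.94 ± 0.09), and ETT (−0.65 ± 0.08) and ARF10 (−0.71 ± 0.09) fell. Among 11 GH3 and receptor genes, 0 rose and 2 fell, with 1 and 2 adjusted over the list alone (camera adjusted p = 0.676; adjusted p = 0.773 with an estimated correlation). The auxin-conjugating enzyme gene GH3.5 fell (−1.25 ± 0.15). Among 48 SAUR genes, 2 rose and 1 fell, also over the list alone (camera adjusted p = 0.825 with a downward direction, fry upward; adjusted p = 0.817 with an estimated correlation). SAUR29 (−2.05, n = 3) rested on 1 array, with values of 0.05, −0.12 and −4.07, and lost its call without the dye term (−1.38, adjusted p = 0.417).

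The root pole and vascular lists were called lower at 3 d at the preset correlation alone, while shoot apex genes went both ways. Of 12 root pole and ground tissue genes, 6 fell and 0 rose, with 7 and 0 adjusted over the list alone (median −0.59, camera adjusted p = 0.0189; adjusted p = 0.257 with an estimated correlation). PLT1, a root stem-cell factor, fell 2.57-fold (−1.36 ± 0.07), and the zinc-finger gene JKD fell 4.28-fold (−2.10 ± 0.09, n = 3). SHR, a ground tissue regulator, was not well above background in the bdl cross on any array and was at least 2.46-fold lower (adjusted p = 0.0327); the call ended with the blank-spot dye term (adjusted p = 0.107). Of 12 vascular genes, 5 fell and 0 rose, with 6 and 0 adjusted over the list alone (median −1.07, camera adjusted p = 0.00154; adjusted p = 0.577 with an estimated correlation). AHP6, the cytokinin-activating enzyme gene LOG4 (−2.35 ± 0.21) and the bHLH gene T5L1 (−1.57 ± 0.20) fell, though T5L1 lost its call with the blank-spot dye term (adjusted p = 0.0542). Among 21 shoot apex and cotyledon genes, 3 rose and 5 fell, with 6 and 6 adjusted over the list alone (median −0.35, mean −0.00, camera adjusted p = 0.362; adjusted p = 0.650 with an estimated correlation). STM, a shoot meristem homeobox gene, rose 2.25-fold (1.17 ± 0.07), while FIL (−3.07 ± 0.27), AGO10 (−1.29 ± 0.07) and PHB (−0.99 ± 0.08) fell.

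Other patterning and hormone lists did not pass at 3 d. Of 12 epidermis genes, 1 rose and 2 fell, with 3 and 4 adjusted over the list alone (median 0.03, mean −0.06, camera adjusted p = 0.943 downward; adjusted p = 0.947 with an estimated correlation). HDG2 rose (0.70 ± 0.06) and PDF1 fell (−1.15 ± 0.13). Of 11 zygote and suspensor genes, 5 rose and 1 fell, with 5 and 2 adjusted over the list alone (median 0.13, camera adjusted p = 0.409; adjusted p = 0.683 with an estimated correlation). WOX8, a homeobox gene of the basal lineage, rose 1.91-fold (0.93 ± 0.08) and PIN7 fell. Among 8 genes of the suspensor bHLH list, 1 rose and 1 fell, with 3 and 4 adjusted over the list alone. Its median was −0.32 and its mean 0.05 (camera adjusted p = 0.943 downward, and 0.947 with an estimated correlation). AT3G57800 rose (0.80 ± 0.10), but not in the mean over probes (adjusted p = 0.0569). Cytokinin response gave 1 rise and 2 falls of 10, with 3 and 3 adjusted over the list alone (median 0.27, mean −0.45, camera adjusted p = 0.825 upward, fry downward; adjusted p = 0.817 with an estimated correlation). Gibberellin metabolism gave 0 rises and 1 fall of 6, also over the list alone (camera adjusted p = 0.610; adjusted p = 0.817 with an estimated correlation), the fall being that of GA2OX2, which read −1.30 ± 0.14 with a signal above blank spots in the bdl cross on 1 of 4 arrays.

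Seed storage genes had the highest median of the 23 lists at 3 d. Of 13 storage and oil body genes, 11 rose, 0 fell and 2 did not pass, also adjusted over the list alone (median 3.51, camera adjusted p = 2.04e-08; adjusted p = 0.257 with an estimated correlation). Besides SESA3 and OLEO4, SESA4 rose 11.3-fold, AT3G01570 11.9-fold (3.57 ± 0.06) and OLEO1 4.74-fold (2.24 ± 0.07). Replicate 4 was lower than the other arrays in several members, as in OLEO2 (1.40, others 2.63 to 2.84), OLEO3 (1.51, others 2.53 to 2.74), SESA5 (2.42, others 4.63 and 4.86) and CRA1 (4.21, others 5.11 and 5.68). Over bright probes that array correlated with the others at 0.768 to 0.800, against 0.920 to 0.953 among them. Among 11 maturation regulators, 4 rose and 2 fell, with 4 and 3 adjusted over the list alone (median 0.15, camera adjusted p = 0.395; adjusted p = 0.647 with an estimated correlation). L1L (1.27 ± 0.15), the oil synthesis regulator WRI1 (1.13 ± 0.07), FUS3 (0.90 ± 0.06) and LEC1 (0.54 ± 0.07) rose, LEC1 not without the filter on dim probes (adjusted p = 0.0511), and ABI3 fell (−0.89 ± 0.07). Markers of other tissues moved in the direction of the storage genes. Of 14 seed coat genes, 4 rose and 0 fell, with 5 and 0 adjusted over the list alone (median 0.38, camera adjusted p = 0.00398; adjusted p = 0.257 with an estimated correlation), led by the chalcone synthase gene TT4 (0.88 ± 0.08). Of 11 endosperm genes, 2 rose and 0 fell, with 3 and 0 adjusted over the list alone (median 0.19, camera adjusted p = 0.0391; adjusted p = 0.284 with an estimated correlation), namely MPC (1.13 ± 0.08) and AGL36 (1.39 ± 0.17). The endosperm call ended in the value table (adjusted p = 0.0553) and without replicate 4 (adjusted p = 0.0656).

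Camera called the photosynthesis list higher at 3 d, and the division and ribosomal protein lists lower, at the preset correlation alone. Of 38 photosynthesis genes, 18 rose and 1 fell, with 31 and 1 adjusted over the list alone (median 0.52, camera adjusted p = 1.07e-09; adjusted p = 0.231 with an estimated correlation). LHCB3 (0.93 ± 0.06), a light-harvesting protein gene, and PORC (1.05 ± 0.06), of chlorophyll synthesis, were among them. Of 26 cell division and DNA replication genes, 7 fell and 0 rose, with 13 and 0 adjusted over the list alone (median −0.34, camera adjusted p = 2.44e-06; adjusted p = 0.231 with an estimated correlation). The D-type cyclin genes CYCD3;2 (−1.27 ± 0.07) and CYCD3;1 (−1.13 ± 0.08) fell most among the named members. Of 217 cytosolic ribosomal protein genes, 65 fell and 1 rose, with 107 and 3 adjusted over the list alone (median −0.35, camera adjusted p = 1.3e-15; adjusted p = 0.231 with an estimated correlation). AT2G44860 (−1.12 ± 0.08) and AT3G55750 (−1.13 ± 0.07) were examples. Heat shock and wounding genes, which respond to handling, gave 4 rises and 0 falls of 15, with 6 and 1 adjusted over the list alone (median 0.39, camera adjusted p = 0.0189; adjusted p = 0.257 with an estimated correlation). HSP70 rose 3.11-fold (1.64 ± 0.09), and the list's call ended without replicate 3 (adjusted p = 0.0688). In all, camera called 12 of 23 lists at 3 d and 0 with an estimated correlation (3 at an unadjusted p under 0.05), and fry called 13. The form with an estimated correlation has few degrees of freedom here, so its 0 calls do not show that correlation among genes made the others.

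**Figure D2:**
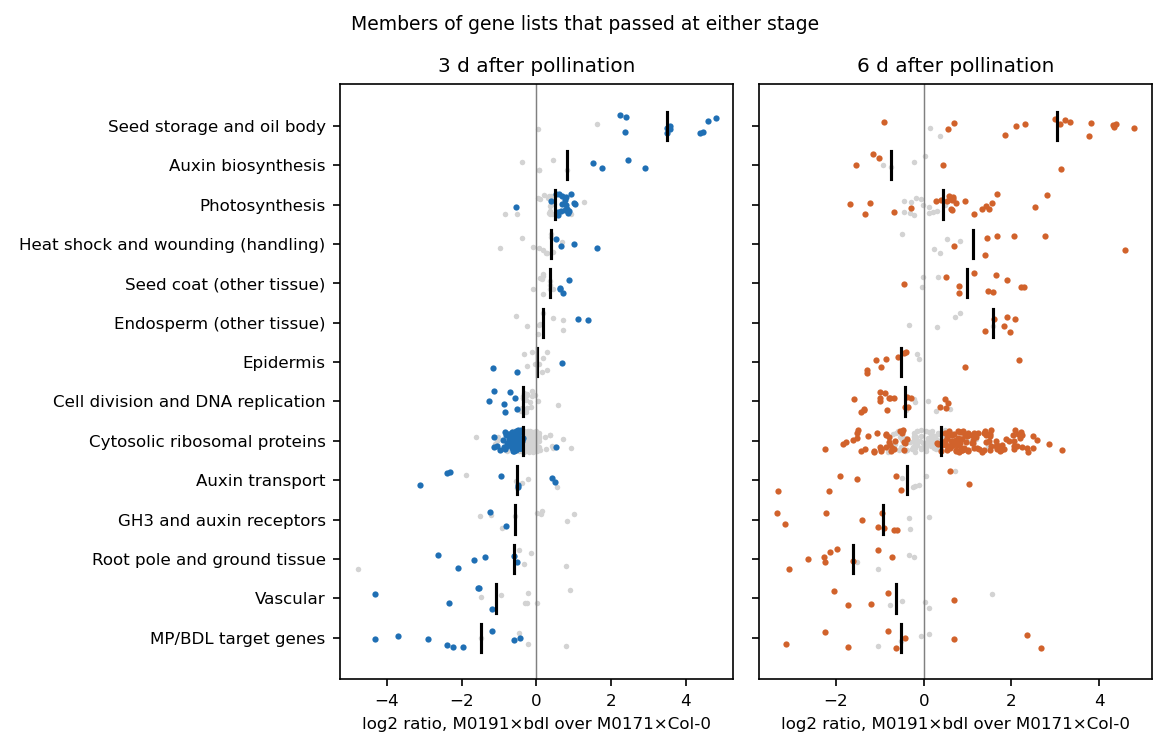
Log2 ratio of the bdl cross over the Col-0 cross (horizontal axis) for members of the 14 lists that passed at 3 d or 6 d (vertical axis), with 1 point per gene, coloured where the gene passed and grey where it did not, and a black bar at the list's median. Storage genes have medians of 3.51 at 3 d and 3.05 at 6 d, and ribosomal protein genes have medians of −0.35 and 0.39.

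The comparison at 6 d put the same question to older embryos, and it found differences in most genes. Camera called storage genes and markers of seed coat and endosperm as higher, and GH3 and receptor genes and root pole genes as lower, but none of them with an estimated correlation (adjusted p = 0.386 to 0.419). Of 19986 genes tested, 5329 rose and 5336 fell, 10665 in all (53.4%), of which 2998 rose and 2005 fell by at least 1 on the log2 scale. The direction at this stage rests on the table's shared convention. Among the largest rises were the ERF-type factor Rap2.6L (55.6-fold, 5.80 ± 0.78), AT5G16230 (35.1-fold, 5.14 ± 0.41), AT1G51850 (34.3-fold, 5.10 ± 0.99), AT4G28405 (34.0-fold, 5.09 ± 0.16), AT5G55132 (33.2-fold, 5.05 ± 0.18) and AT1G65490 (32.9-fold, 5.04 ± 0.07). Among the largest falls were PTF1 (32.9-fold, −5.04 ± 0.28), AT2G45340 (38.5-fold, −5.27 ± 0.86), AT1G05577 (32.0-fold) and the lipase gene LTL1 (18.1-fold, −4.18 ± 0.70). The probe of PTF1 was not above blank spots on any 3 d array in either channel. Replicate 3 weighed on several falls, which without it were −4.19 for AT2G45340, −4.05 for AT1G05577 and −3.30 for LTL1; with 1 array left out Rap2.6L read 4.87 to 6.72 and AT1G51850 3.86 to 6.35. Calls ended without replicate 2 for Rap2.6L (adjusted p = 0.0616), without replicates 3 or 4 for AT1G51850 (adjusted p = 0.0979 and 0.0876), and without replicates 1 or 2 for AT2G45340 (0.0755 and 0.0807), AT1G05577 (0.0710 and 0.0688) and LTL1 (0.0792 and 0.0829). With 1 array left out, the count of genes was 7150 to 8416. These fits kept the dye term and had 1 residual degree of freedom, so a call at 6 d can end through that loss as well as through the array.

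GH3 enzymes and auxin receptors fell together at 6 d. Of 12 genes, 9 fell and 0 rose, also adjusted over the list alone (median −0.93, camera adjusted p = 0.00443; adjusted p = 0.386 with an estimated correlation). The conjugating enzyme genes DFL1 (10.2-fold, −3.36 ± 0.31), GH3.5 (−3.17 ± 0.14) and GH3.3 (4.71-fold, −2.23 ± 0.10) and the receptor gene AFB5 (−1.40 ± 0.06) fell, while GH3.1 (−0.34), GH3.4 (0.13) and DFL2 (−0.32) did not pass. Of 16 ARF genes, 3 rose and 10 fell, with 4 and 10 adjusted over the list alone (median −0.47, camera adjusted p = 0.166; adjusted p = 0.422 with an estimated correlation). Of 14 transport genes, 2 rose and 6 fell, also over the list alone (median −0.38, camera adjusted p = 0.182; adjusted p = 0.441 with an estimated correlation); PIN3 fell 9.99-fold (−3.32 ± 0.21), LAX2 4.47-fold and PIN7 3.76-fold (−1.91, or −0.63 in the mean over probes). The 23 Aux/IAA genes gave 6 rises and 4 falls, also over the list alone (median −0.05, camera adjusted p = 0.936 downward, fry upward; adjusted p = 0.939 with an estimated correlation). IAA16 rose (1.17 ± 0.10) and IAA26 fell (−2.12 ± 0.13), while IAA13 read 0.92 in its brightest probe and −1.04 (adjusted p = 0.00359) in the mean over probes. The 9 biosynthesis genes gave 2 rises and 3 falls, also over the list alone (median −0.74, camera adjusted p = 0.9497 upward; adjusted p = 0.964 with an estimated correlation). YUC10 rose 8.74-fold (3.13 ± 0.14), YUC3 (−1.55 ± 0.09, n = 3) fell, and TAA1 read 0.02 ± 0.10 (adjusted p = 0.894). The 43 SAUR genes gave 14 rises and 4 falls, with 11 and 3 adjusted over the list alone (median 0.27, camera adjusted p = 0.344; adjusted p = 0.534 with an estimated correlation), SAUR19 rising 2.98-fold (1.58 ± 0.07).

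MP/BDL target genes did not pass as a list at 6 d, though the difference from 3 d did not pass either (camera adjusted p = 0.0647; adjusted p = 0.463 with an estimated correlation). Of 13 targets, 3 rose, 6 fell and 4 did not pass, also adjusted over the list alone (median −0.51, camera adjusted p = 0.467; adjusted p = 0.730 with an estimated correlation). DRNL rose 6.42-fold (2.68 ± 0.07) and DRN 5.11-fold (2.35 ± 0.23). AHP6 rose 1.60-fold (0.68 ± 0.09, adjusted p = 0.0127), a call that ended without replicate 2 (0.62, adjusted p = 0.0568). SCZ (−2.26 ± 0.08), HB-8 (−1.73 ± 0.11) and TMO6 (−0.82 ± 0.07) fell. CRF2 read −0.07 ± 0.08, with another probe at 2.09. TMO7, named after its values were seen, read −3.15 ± 0.28 (n = 3, adjusted p = 0.0158).

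Root pole and epidermis genes fell at 6 d, and shoot apex genes went both ways. Of 13 root pole genes, 9 fell and 0 rose, with 11 and 0 adjusted over the list alone (median −1.61, camera adjusted p = 0.00443; adjusted p = 0.419 with an estimated correlation); PLT1 fell 6.25-fold (−2.64 ± 0.07), JKD 3.95-fold (−1.98 ± 0.18) and SCR 2.05-fold (−1.04 ± 0.08). Of 12 epidermis genes, 8 fell and 2 rose, also over the list alone (median −0.52, camera adjusted p = 0.0299; adjusted p = 0.420 with an estimated correlation). The homeodomain genes ATML1 (−1.30 ± 0.08) and PDF2 (−1.08 ± 0.06), which specify epidermis, fell; the list's call ended without replicates 1, 3 or 4 (adjusted p = 0.0533, 0.0568 and 0.0792). Of 21 shoot apex genes, 6 rose and 9 fell, with 6 and 10 adjusted over the list alone (median −0.29, camera adjusted p = 0.354; adjusted p = 0.598 with an estimated correlation). CUC1 (5.06-fold, 2.34 ± 0.07), CLV3 (4.73-fold, 2.24 ± 0.10) and STM (2.72-fold, 1.44 ± 0.13) rose, while YAB3 (11.7-fold, −3.55 ± 0.08) and AS1 (9.38-fold, −3.23 ± 0.07) fell. Of 10 vascular genes, 1 rose and 4 fell, also over the list alone (median −0.63, camera adjusted p = 0.344; adjusted p = 0.598 with an estimated correlation), with LHW at −2.04 ± 0.15.

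The small lists of the basal lineage and of other hormones did not pass at 6 d. Of 7 genes of the suspensor bHLH list, 2 rose and 3 fell, also over the list alone. Its median was −0.66 (camera adjusted p = 0.597, and 0.708 with an estimated correlation). Of 12 zygote and suspensor genes, 3 rose and 3 fell, also over the list alone (median 0.19, camera adjusted p = 0.731 upward, fry downward; adjusted p = 0.798 with an estimated correlation). Of 11 cytokinin response genes, 6 rose and 3 fell, with 6 and 4 adjusted over the list alone (median 0.68, camera adjusted p = 0.467; adjusted p = 0.598 with an estimated correlation); the response regulator ARR15 rose 3.87-fold (1.95 ± 0.07) and ARR7 fell 2.32-fold (−1.21 ± 0.06). Of 7 gibberellin genes, 3 rose and 2 fell, also over the list alone (median 0.12, mean −0.34, camera adjusted p = 0.673 upward; adjusted p = 0.798 with an estimated correlation), with GA20OX3 at 1.44 ± 0.07 and GA2OX2 at −1.83 ± 0.08.

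Storage genes rose at 6 d beside markers of endosperm and seed coat. Of 18 storage and oil body genes, 15 rose and 1 fell, also adjusted over the list alone (median 3.05, camera adjusted p = 9.36e-05; adjusted p = 0.386 with an estimated correlation). SESA3 rose 27.8-fold (4.80 ± 0.22), SESA4 20.1-fold (4.33 ± 0.14) and OLEO1 4.96-fold (2.31 ± 0.06), and OLEO4 rose 1.47-fold (0.56 ± 0.07). The fall was that of TAG1 (−0.92 ± 0.06), an acyltransferase gene of oil synthesis named after its value was seen. Of 11 endosperm genes, 6 rose and 0 fell, with 8 and 0 adjusted over the list alone (median 1.57, camera adjusted p = 0.00838; adjusted p = 0.386 with an estimated correlation), among them PHE1 (4.26-fold, 2.09 ± 0.16) and ZOU (3.91-fold, 1.97 ± 0.09). Of 14 seed coat genes, 10 rose and 1 fell, also over the list alone (median 0.98, camera adjusted p = 0.00838; adjusted p = 0.413 with an estimated correlation), among them TT3 (4.85-fold, 2.28 ± 0.07), TT10 (4.66-fold, 2.22 ± 0.11) and BAN (3.00-fold, 1.58 ± 0.06). Of 12 heat shock and wounding genes, 7 rose and 0 fell, with 8 and 0 adjusted over the list alone (median 1.12, camera adjusted p = 0.0115; adjusted p = 0.386 with an estimated correlation), JAZ1 rising 4.19-fold (2.07 ± 0.09). Of 11 maturation regulators, 6 rose and 2 fell, also over the list alone (median 0.71, camera adjusted p = 0.225; adjusted p = 0.598 with an estimated correlation), with LEC2 at 0.82 ± 0.06 and ABI4 at −1.29 ± 0.07.

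At 6 d camera called the photosynthesis and ribosomal protein lists higher, and the division list lower, at the preset correlation alone. Of 38 photosynthesis genes, 20 rose and 5 fell, also adjusted over the list alone (median 0.44, camera adjusted p = 0.0299; adjusted p = 0.386 with an estimated correlation). PSAK rose 7.04-fold (2.82 ± 0.06); the list's call ended without replicates 1 or 4 (adjusted p = 0.0672 and 0.0792). Of 218 ribosomal protein genes, 101 rose and 34 fell, with 105 and 36 adjusted over the list alone (median 0.39, camera adjusted p = 0.004; adjusted p = 0.413 with an estimated correlation), such as AT3G28500 (8.85-fold, 3.15 ± 0.08). Of 26 division genes, 16 fell and 4 rose, also over the list alone (median −0.42, camera adjusted p = 0.0176; adjusted p = 0.386 with an estimated correlation), such as PCNA2 (−1.58 ± 0.10) and MCM4 (−1.36 ± 0.08), which act in DNA replication. In all, camera called 10 of 23 lists at 6 d and 0 with an estimated correlation (0 at an unadjusted p under 0.05). Fry called 18, without comparing them with other genes, at a stage where 53.4% of all genes were called.

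The stages were compared to ask which differences between the crosses changed from 3 d to 6 d. The MP/BDL targets DRNL, DRN and AHP6 turned from lower to higher, and camera called ribosomal protein genes as a list (adjusted p = 6.86e-08; adjusted p = 0.250 with an estimated correlation). Of 18843 genes, 4500 were higher and 3910 lower at 6 d relative to 3 d, 8410 in all (44.6%). DRNL changed most (5.58, adjusted p = 6.9e-06), with AHP6 (5.01, adjusted p = 1.83e-05), DRN (4.31, adjusted p = 4.34e-05) and IAA19 (4.11, adjusted p = 8.68e-05), each of which fell at 3 d and rose at 6 d. IAA19 at 6 d lost its call without replicates 3 or 4 (adjusted p = 0.112 and 0.106). ARD3 went the other way, from 3.61 ± 0.11 (no call with the blank-spot dye term, adjusted p = 0.0542) to −0.96 ± 0.07 (difference −4.57, adjusted p = 0.000705), and OLEO4 went from 4.39 to 0.56 (−3.84, adjusted p = 0.000103). TAA1 (−1.49, adjusted p = 0.000194) and YUC4 (−2.48, adjusted p = 0.000343) were lower at 6 d than at 3 d. YAB3 (−3.20, adjusted p = 1.82e-05) and AS1 (−2.86, adjusted p = 2.22e-05) also dropped, while SESA3 (0.19, adjusted p = 0.607) and SESA1 (−0.17, adjusted p = 0.658) did not pass.

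As a list, cytosolic ribosomal protein genes had a median of −0.35 at 3 d and 0.39 at 6 d, with 151 members not passing at 3 d and 83 at 6 d. Of 217, 121 were higher and 18 lower at 6 d, with 122 and 22 adjusted over the list alone (median 0.73, camera adjusted p = 6.86e-08; adjusted p = 0.250 with an estimated correlation). AT1G74270 moved from −0.46 ± 0.07 (no call after median centring, adjusted p = 0.0524) to 2.24 ± 0.06 and AT1G34030 from −0.86 ± 0.07 to 1.12 ± 0.09. GH3 and receptor genes were lower at 6 d in 5 of 11 and higher in 0, with 8 and 0 adjusted over the list alone (median −1.05, camera adjusted p = 0.0467; adjusted p = 0.250 with an estimated correlation). Epidermis genes were lower in 8 of 12 and higher in 2, also over the list alone (median −0.55, camera adjusted p = 0.0467; adjusted p = 0.250 with an estimated correlation). Camera called 3 of 23 lists, 0 with an estimated correlation (3 at an unadjusted p under 0.05), and fry called 16. Median, mean or test differed in sign for zygote genes (median 0.13, mean −0.09), shoot apex genes (0.06 and −0.07), gibberellin genes (median −0.28, camera upward) and division genes (camera downward, fry upward), none of which passed. Scale normalization turned the medians of zygote, gibberellin, division and root pole genes and of maturation regulators in this comparison, to −0.13, 0.06, 0.29, 0.15 and −0.22. It also brought the medians of the called lists to −0.46 for GH3 and receptor genes, −0.25 for epidermis and 0.82 for ribosomal proteins, and that of storage genes, which did not pass, from −0.36 to −2.81.

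Effects at the stages were related across genes, with a Pearson r of 0.325 and a Spearman rho of 0.330 over 18843 genes, which are not independent replicates. Among 18256 genes tested at both stages, 782 rose at both and 634 fell at both, against 357.4 and 321.2 for independent lists. Another 110 rose and then fell, and 218 fell and then rose, against 353.2 and 325.1. The genes of largest mean change called at both stages were LEA7, PAP85, SESA2, SESA3 and AT5G44630, all of them higher in the bdl cross, though AT5G44630 lost its 3 d call with no filter on dim probes, in the value table and under loess with scale normalization (adjusted p = 0.0533, 0.0529 and 0.0524).

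**Figure D3:**
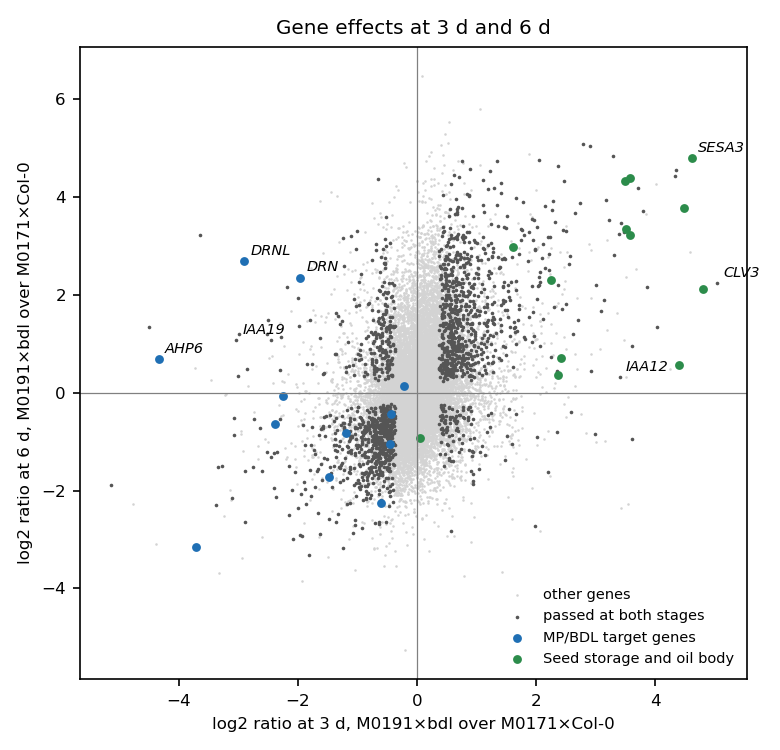
Log2 ratio of the bdl cross over the Col-0 cross at 3 d (horizontal axis) against 6 d (vertical axis), with 1 point per gene, dark where the gene passed at both stages, blue for MP/BDL targets and green for storage genes. Most storage genes lie high on both axes, as SESA3 does at 4.61 and 4.80, whereas DRNL lies at −2.90 and 2.68.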

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

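The tests of carry-over, cross-hybridisation, dyes, shared RNA and turned ratios were chosen only after the results were seen, whereas the splits of the arrays were planned.

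Storage and oil body genes were higher in the bdl cross at both stages, with medians of 3.51 and 3.05. Carry-over of endosperm or seed coat as the whole cause was examined with their 25 markers, which rose less than the storage genes. The markers had a median of 0.38 at 3 d and 1.39 at 6 d (MAD 0.402 and 0.862), below the storage genes by 3.13 and 1.66. At either stage 0 markers lay above the storage median. This gap cannot decide the question, because a ratio also depends on how much signal the Col-0 cross already held for each gene. Cross-hybridisation among 2S albumin genes as the whole cause is argued against, since 6 of 8 other storage genes rose at 3 d and 10 of 13 at 6 d. Whether the 2S albumin probes read each other's transcripts cannot be told from those genes. Carry-over may add to the rise, since 22 of the 25 markers read above 0 at 3 d and 21 at 6 d. A difference brought by either parent line, such as an earlier onset of storage, stays open as an untested biological explanation.

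Dim probes of the 3 d arrays paired replicates 1 with 4 (r = 0.216) and 2 with 3 (r = 0.233), against −0.136 to −0.006 for other pairs over 5071 probes, which is not how the labels give the dyes. Dyes that ran otherwise than the labels say would also part bright probes that way, and over 6240 bright probes that contrast had the largest SD of the pairings, 0.108 against 0.0902 for the labels' dyes and 0.0888 for the remaining pairing. This is consistent with columns whose dyes differ from the labels, though an order of scanning or hybridisation shared by those arrays could do the same and was not tested. Shared RNA of replicates 1 and 4 (bright-probe r = 0.800) or of 2 and 3 (r = 0.953) cannot be told apart from these, since replicate 4 was low with every array (0.768 with 2 and 0.773 with 3) and replicate 1 was closer to 3 (0.922). No biological explanation was tested, and 4872 genes were called at 3 d with a dye term that followed the blank spots. The same pairs had the highest r over 5071 dim probes at 6 d, by less. Replicates 1 and 4 read 0.461 and 2 and 3 read 0.405, against 0.313 to 0.371 for other pairs. Over 6462 brighter probes at 6 d, 1 and 4 stayed highest (0.697), but 2 and 3 lay below 1 and 3 (0.658) and 3 and 4 (0.612). No 6 d fit was run with a dye term that followed this pairing.

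DRN, DRNL and AHP6 fell at 3 d and rose at 6 d. Cross-hybridisation between the paralogs DRN and DRNL cannot be told apart from a turn of each, since their log2 ratios had the same sign at each stage and DRN minus DRNL was 0.94 at 3 d and −0.33 at 6 d. Ratios deposited the other way round at 6 d could turn these genes too; 1416 genes passed in the same direction at both stages and 328 in opposite directions, against 678.6 and 678.3 for independent lists, and turned ratios cannot be told apart from true opposition by that count, because no 6 d signals were used here. IAA12 and the storage genes, which were higher at both stages, would then have turned as well. A change in how embryos of these crosses differ with age is an untested biological explanation.

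Turning the signs of arrays gave 8 patterns per stage, the real pattern included, and only 1 reached the real count in each case. At 3 d limma called 2527 genes and at most 0 under another pattern, and at 6 d 10665 and at most 0; camera called 12 lists against at most 8 and 10 lists against at most 8. These patterns are too few for a share under 0.05. Turning arrays also adds the difference between crosses to the spread, which holds gene counts down. Turning replicates 3 and 4 instead moves that difference into the dye term, so that pattern tests the dyes. Patterns that turned 1 array, and so kept part of the contrast, called 4 to 8 lists at both stages. For the stage difference, 1 of 34 splits of the 8 arrays reached the real count of 8410 genes, the highest other count being 2. Every other split mixed arrays of both stages within a group, which adds the stage difference to the spread and holds its count down. The splits argue, at that share, only against a chance division of the arrays. A batch shared by the arrays of a stage was not tested.

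Among 265 groups of 4 values, 14 (5.28%) held an array that stood apart from the others, and chance sets apart about 1 in 20. At 3 d these were PSAO with 0.48 on replicate 1 (others 0.93 to 0.99), AT1G15760 with −5.01 on replicate 1 (−2.96 to −2.68), WRI1 with 1.28 on replicate 1 (1.06 to 1.09), FUS3 with 0.80 on replicate 2 (0.92 to 0.94) and YUC4 with 2.19 on replicate 4 (3.09 to 3.26). At 6 d, replicate 3 stood apart in AT1G79420 with −7.65 (−2.81 to −2.71), AT2G45340 with −8.22 (−4.57 to −3.90), PTF1 with −6.17 (−4.78 to −4.52), AT3G63040 with 3.79 (4.27 to 4.34) and SESA1 with 2.99 (3.43 to 3.52). Replicate 1 stood apart at 6 d in ETT with 0.13 (0.30 to 0.33) and YUC4 with 0.27 (0.49 to 0.53), and replicate 2 in YUC6 with −1.50 (−1.06 to −0.98) and TCH2 with 1.21 (3.18 to 3.42).

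The difference between crosses changed between the stages in 8410 genes, and in 3 lists: GH3 enzymes and receptors (camera adjusted p = 0.0467), epidermis (0.0467) and ribosomal proteins (6.86e-08), each with an adjusted p = 0.250 with an estimated correlation. Named genes called in opposite directions, with 6 d minus 3 d, were DRNL (5.58), AT5G50050 (5.02), AHP6 (5.01), DRN (4.31), IAA19 (4.11), AT1G53860 (3.34), AT1G74270 (2.70), AT3G02190 (2.65), AT3G11120 (2.64), AT1G34030 (1.97), IAA20 (1.44) and ETT (0.92), and on the falling side AT1G09750 (−4.72), ARD3 (−4.57) and ARF13 (−2.68). Their 6 d calls ended without any of the 4 arrays for ETT (adjusted p = 0.0919 to 0.160; 0.0518 in the mean over probes) and AT1G53860 (0.0728 to 0.109), without replicates 1 or 2 for IAA20 (0.0661 and 0.0600), 3 or 4 for IAA19 (0.112 and 0.106) and 2 for AHP6 (0.0568), and in a fit of all 8 arrays for ARD3 (0.0653). At 3 d calls ended with the dye term kept and any array left out for all of them, and under other alternatives for AT1G74270 (adjusted p up to 0.0627), AT3G02190 (0.0577), AT5G50050 (0.0559), ARD3 (0.0733) and ARF13 (0.0544). Another 98 named genes also passed the test of the difference, of 164 tested.

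Signals outside the comparisons were seen in 36 of 75 microRNA stem-loop probes with no locus, which lay above blank spots on 2 or more of the 3 d arrays. Print-control spots had a median signal in the bdl cross of at least 1374 on the 3 d arrays.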

How the results depend on the processing

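At 3 d the blank-spot dye term, global loess alone and the fits without both the dye term and an array, and at 3 d and 6 d the intensity trend, were tests chosen only after the data were seen. The count of 2527 genes at 3 d became 5375 with both channels above blank spots on all 4 arrays, 5078 without the dye term, 4872 with the blank-spot dye term, 5732 with an intensity trend and 660 at an absolute log2 ratio of at least 1; other settings gave 1741 to 2648. The larger effect is a stricter rule by construction; for the others the cause was not tested. Leaving out 1 array gave 0 to 3969 genes: limma called 0 with the dye term kept (4610 to 5358 at an unadjusted p under 0.05; 1 residual degree of freedom), and without it 2748, 1973, 2046 and 3969 for replicates 1 to 4. At 6 d the count of 10665 fell to 5003 at an absolute log2 ratio of at least 1, again by construction, and otherwise lay between 7150 and 11631. Lists passing numbered 11 to 13 at 3 d and 8 to 10 at 6 d. The exception was camera with an estimated correlation, which called 0 at each stage (3 and 0 at an unadjusted p under 0.05, fry 13 and 18). At 3 d the estimate lay below the preset 0.01 for division genes (−0.021) and root pole genes (−0.125). Camera's unadjusted p still rose, from 4.25e-07 to 0.0301 and from 0.00826 to 0.112, so a higher correlation does not account for those losses. With an estimate, camera's p-values rest on the few residual degrees of freedom of a 4-array fit, and with the preset on the number of genes. That change accounts for the losses of the division and root pole lists, and it applies to every list. Ribosomal protein genes at 3 d went from an unadjusted camera p of 5.64e-17 to 0.0185, with an estimate of 0.015. For storage genes (0.383) and vascular genes (0.729) the estimate was higher, and the shares of the correlation and of the degrees of freedom were not separated. IAA12 at 3 d read 3.35 to 3.45 without an array and 2.65 in the mean over probes; at 6 d it read 0.29 to 0.34, and 0.14 in the mean over probes, which takes in a probe at −0.61. In the mean over probes at 6 d, AT1G68920 (−0.13) and IAA13 (−1.04) reversed, because their probes disagree. The count for the stage difference lay between 6293 and 8732. With the replicate block it was 7369. After each gene's mean over the arrays of a stage was taken off, same-numbered arrays of the stages correlated at −0.040, −0.043, −0.079 and −0.074. Each 3 d array correlated more closely with a 6 d array of another number (0.039 to 0.106). These deviations gave no sign of pairing by number, which does not exclude it. The correlation of the stages lay between 0.325 and 0.334. Of named genes called, 107 of 107 at 3 d, 148 of 150 at 6 d and 10 of 10 for the stage difference kept their direction under every alternative run; 0, 113 and 8 also kept their call. All 12 and 10 lists kept their direction, and 0 kept their call under every one. Medians of all genes moved by less than 0.1 under each scaling. Uncorrected background, plain subtraction and print-tip loess were not run. Signal over background limits the dim probes: at 3 d, 74.3% to 81.2% of gene spots lay above blank spots.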

Other observations

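All tests of gene families here were chosen only after the data were seen, as 29 families drawn from gene descriptions, and none of them passed with an estimated correlation. Genes of pentatricopeptide repeat proteins, which process organelle RNA, were lower in the bdl cross, above all at 6 d. Of 383 measured at 6 d, 211 fell and 12 rose (median −0.68, camera adjusted p = 5.43e-12; adjusted p = 0.185 with an estimated correlation), and of 324 at 3 d, 26 fell and 2 rose, 0 and 0 adjusted over the family alone, where 1178 of all 19229 genes fell (median −0.27, camera adjusted p = 2.52e-05; adjusted p = 0.370 with an estimated correlation). The difference was lower at 6 d in 107 of 339 and higher in 12 (camera adjusted p = 0.000216; adjusted p = 0.101 with an estimated correlation). Of 10000 random lists matched on brightness, 0 had a median as low at either stage, the lowest being −0.10 at 3 d and −0.23 at 6 d. Those lists drew genes independently, so they allow neither for genes of a family varying together nor for the choice of this family among 29. Examples at 6 d were PTAC2 (−1.83 ± 0.06), PRORP1 (−2.05 ± 0.07) and BIR6 (−1.67 ± 0.07), while AT1G07590 rose (3.92 ± 0.11).

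Lipid transfer proteins and MADS-box factors were higher at 6 d. Of 78 lipid transfer genes, 39 rose and 4 fell (median 0.53, camera adjusted p = 0.000507; adjusted p = 0.399 with an estimated correlation), among them AT5G38195 (4.74 ± 0.08), LTP4 (4.00 ± 0.12) and LTP2 (3.97 ± 0.09). Of 59 MADS-box genes, 24 rose and 4 fell (median 0.51, camera adjusted p = 0.00583; adjusted p = 0.399 with an estimated correlation), including AGL102 (3.27 ± 0.09), the ovule and seed gene STK (2.02 ± 0.06) and the flowering repressor FLC (1.51 ± 0.06). The MADS-box family also holds the endosperm genes PHE1 (2.09) and PHE2 (1.39), and markers of endosperm and seed coat rose too (medians 1.57 and 0.98; adjusted p = 0.386 and 0.413 with an estimated correlation); the lipid transfer family holds the 2S albumin gene SESA5 (4.40). Carry-over of other tissue was not tested for these families. Both families also passed for the stage difference (camera adjusted p = 0.000963 and 0.00537; adjusted p = 0.140 and 0.128 with an estimated correlation). Genes of fatty acid synthesis rose in 13 of 31 and fell in 1 at 3 d (median 0.36, camera adjusted p = 0.000265; adjusted p = 0.370 with an estimated correlation), with ACP5, an acyl carrier protein gene, at 1.87 ± 0.06. Of 51 histone genes at 3 d, 5 fell and 0 rose, 0 and 0 adjusted over the family alone (median −0.24, camera adjusted p = 0.000264; adjusted p = 0.370 with an estimated correlation), while for the stage difference 23 of 49 were higher and 6 lower (camera adjusted p = 0.00825; adjusted p = 0.276 with an estimated correlation), with HTB2 at 2.48 ± 0.12 at 6 d. Pectin methylesterases and their inhibitors rose in 24 of 86 and fell in 4 at 3 d (median 0.44, camera adjusted p = 2.52e-05; adjusted p = 0.370 with an estimated correlation). These medians kept their sign under each scaling run at the stage named, though that of the stage difference of pentatricopeptide repeat genes went from −0.45 to −0.14 under scale normalization.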
